A study of Rattus norvegicus with 12 samples.

How the data were processed

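RNA from 12 cultures of neonatal rat cardiomyocytes was measured on Affymetrix arrays, 1 array per culture. The labels give 6 control and 6 DEHP cultures and call the samples of a group biological replicates, with all cells taken from 1 litter. The tests therefore measure the spread between cultures and arrays, not between litters. Per the submitters' processing notes the arrays were processed with RMA (background correction, normalization and summarization of probes), with no version given. The deposited values are linear ratios. For all 27342 probe sets the median of the log2 ratios over the 12 arrays lay within 1e-04 of 0, so each value is a ratio to the probe set's own median, and the level of a probe set is not held in the values. Column medians ran from 0.99 to 1.02. The number of arrays sets the precision here, since brightness over background is not known.

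The log2 of each deposited ratio was used with no further normalization. Centring a probe set over all arrays leaves differences between groups as they were. Probe sets were named through the platform annotation, with Entrez identifiers matched to a RefSeq gene table of the assembly GRCr8. Of all probe sets, 15097 had 1 gene symbol, 323 had several and 11922 had no gene name in that annotation. The table held 15067 of the identifiers and changed 0 symbols. The sources used here name no genome build for the arrays, so no coordinates are given.

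DEHP was compared with control by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes over all 12 arrays, a two-sided test and Benjamini-Hochberg adjustment over all 27342 probe sets. An adjusted p under 0.05 counted as passing. Log2 folds are DEHP over control and are given ± SE from this fit, with n = 6 arrays per group. Before the data were examined, 34 gene lists were fixed and the tests, the alternatives and the rule for naming genes were written down. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists. The correlation estimated per list and fry were alternatives. On simulated arrays with 200 of 27342 probe sets changed, the limma test recovered 82% of those changed by a log2 fold of 0.5 and 99% of those changed by 1. It made 182 calls, of which 1 was false. The simulated noise was independent between probe sets, so this does not give the rate of false calls in the real comparison. In a simulation of 20 lists with 1 list shifted by 0.5 and no correlation between genes, camera called that list and no other. That simulation does not show how camera does on lists with correlated members, where estimates here reached 0.66.

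Genes were named by a fixed rule. It took the 12 largest rises and 12 largest falls among genes that passed and whose groups did not overlap, leaving out provisional symbols. It also took the members of each list with the smallest p, and Ppara, Pparg, Ppard, Gja1, Myh6, Tnnt2 and Nppa as landmarks. The rule allowed 4 members of a list, of which 3 are printed for a list that passed and 2 for any other. Members beyond these were chosen after their values were seen, and the text says so.

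The plan had assumed log2 expression levels, and 4 steps had to change. A gene with several probe sets, as 499 genes had, took its lowest-numbered one in place of the brightest. No named gene had another probe set that passed in the opposite direction. The minimum level for the largest changes was dropped. The filter on dim probe sets was not run. Robust eBayes replaced eBayes with an intensity trend. Other alternatives were quantile normalization, median centring, cyclic loess, array weights, a minimum fold of 1.2 with limma's treat, an adjusted p under 0.01, the mean of all probe sets of a gene, the replicate number as a block, and each array left out in turn. Alternatives chosen after seeing the data were leaving out control replicate 5 and DEHP replicate 6 together, robust eBayes, and probe sets with 1 gene symbol alone. Plots were drawn with matplotlib 3.10.9.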

Results

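Gene expression was measured in monolayers of heart muscle cells from 2-day-old Sprague-Dawley rats. The cells were grown for 3 days and then kept for another 3 days in 50 µg/mL DEHP or in the vehicle, 0.1% DMSO. DEHP, di(2-ethylhexyl) phthalate, is a plasticizer that leaches from flexible plastic such as medical tubing. The comparison asked which transcripts differ in cardiomyocytes exposed to an amount of DEHP that the submitters call relevant to the clinic. There were 6 control and 6 DEHP arrays, and no other group.

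Under DEHP, genes of mitochondrial fatty acid oxidation were higher, while smooth muscle markers and genes of cardiac stress, cholesterol synthesis and the cell cycle were lower. Tested as lists with an estimated correlation, these had an adjusted p of 0.20, 0.12, 0.018, 0.067 and 0.19 in that order. Pdk4, the kinase that shuts pyruvate out of mitochondrial oxidation, was 10.8-fold higher (log2 fold 3.43 ± 0.06, adjusted p = 1.1e-11). Its log2 ratio was 1.67 ± 0.08 under DEHP and −1.77 ± 0.14 in controls (SD, n = 6 each). Cnn1, the smooth muscle calponin, was 11.2-fold lower (log2 fold −3.49 ± 0.13, adjusted p = 7.74e-09), with 1.64 ± 0.07 in controls and −1.85 ± 0.35 under DEHP (SD, n = 6 each). Edn1, which encodes the vasoconstrictor endothelin-1, was 6.92-fold lower (log2 fold −2.79 ± 0.08).

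The other genes with the largest rises were Cxcl11 (log2 fold 3.13 ± 0.12), Igfbp5 (2.57 ± 0.12), Pla2g7 (2.25 ± 0.12), Acot2 (2.21 ± 0.10), Reg3g (2.13 ± 0.13), Cpt1b (2.12 ± 0.11), Pvalb (2.01 ± 0.10), Hp (1.85 ± 0.28), Ampd3 (1.85 ± 0.17) and Acsl1 (1.85 ± 0.11). Penk, which encodes the precursor of the enkephalin opioid peptides, was also among them as deposited (log2 fold 3.08 ± 0.27), but its log2 fold was −0.01 after cyclic loess normalization. Cyclic loess fits along expression level, which the ratios do not hold, and no other normalization or array left out changed its call. The other largest falls were in Fndc1 (−3.005 ± 0.108), Or51e1 (−2.75 ± 0.15), Xirp2 (−2.66 ± 0.09), Hspb3 (−2.13 ± 0.08), Tgfb3 (−2.08 ± 0.24), Grem1 (−2.06 ± 0.17), Arsi (−2.06 ± 0.13), Prss3bl1 (−2.06 ± 0.12), Agt (−2.05 ± 0.11) and Actg2 (−1.99 ± 0.15). Adjusted p was at most 0.00045 for each of these. The 6 DEHP values of each lay apart from its 6 control values, which the rule that chose these genes required. Agt encodes angiotensinogen, and Grem1 an antagonist of bone morphogenetic proteins.

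Of 14324 genes, 3527 passed the limma test, 2067 higher and 1460 lower under DEHP. At a fold of at least 1.5 these were 406 higher and 400 lower, and at a fold of at least 2 they were 114 and 129. The groups did not overlap in 2422 genes (16.9%), where chance gives 0.216%. Over all 27342 probe sets 5016 passed, 2877 higher and 2139 lower, and 1289 of them had no gene name. Against a minimum fold of 1.2, 870 genes passed. Control replicate 5 and DEHP replicate 6 stood apart, with SDs of log2 ratios of 0.37 and 0.27 against 0.15 to 0.19 in the other arrays. Without both, a setting chosen after seeing the data, 4069 genes passed, 3266 of them shared with the full comparison.

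**Figure D1:**
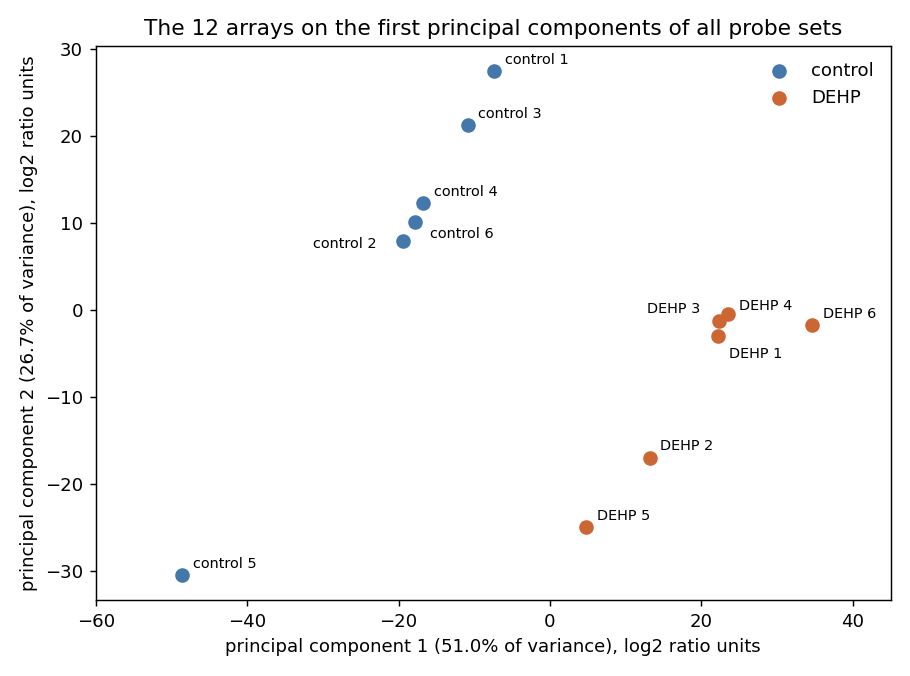
Each point is 1 array, placed by its scores on principal components 1 (51.0% of variance) and 2 (26.7%) of the log2 ratios of all 27342 probe sets. All 6 DEHP arrays (orange) lie to the right of all 6 control arrays (blue), with control replicate 5 far to the left and DEHP replicate 6 farthest to the right.

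Camera called 17 of the 34 fixed lists, 7 higher and 10 lower under DEHP. With an estimated correlation 3 of the 17 passed, namely cardiac stress, integrins and TGF beta, so the p with that estimate is given beside each of the others.

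**Figure D2:**
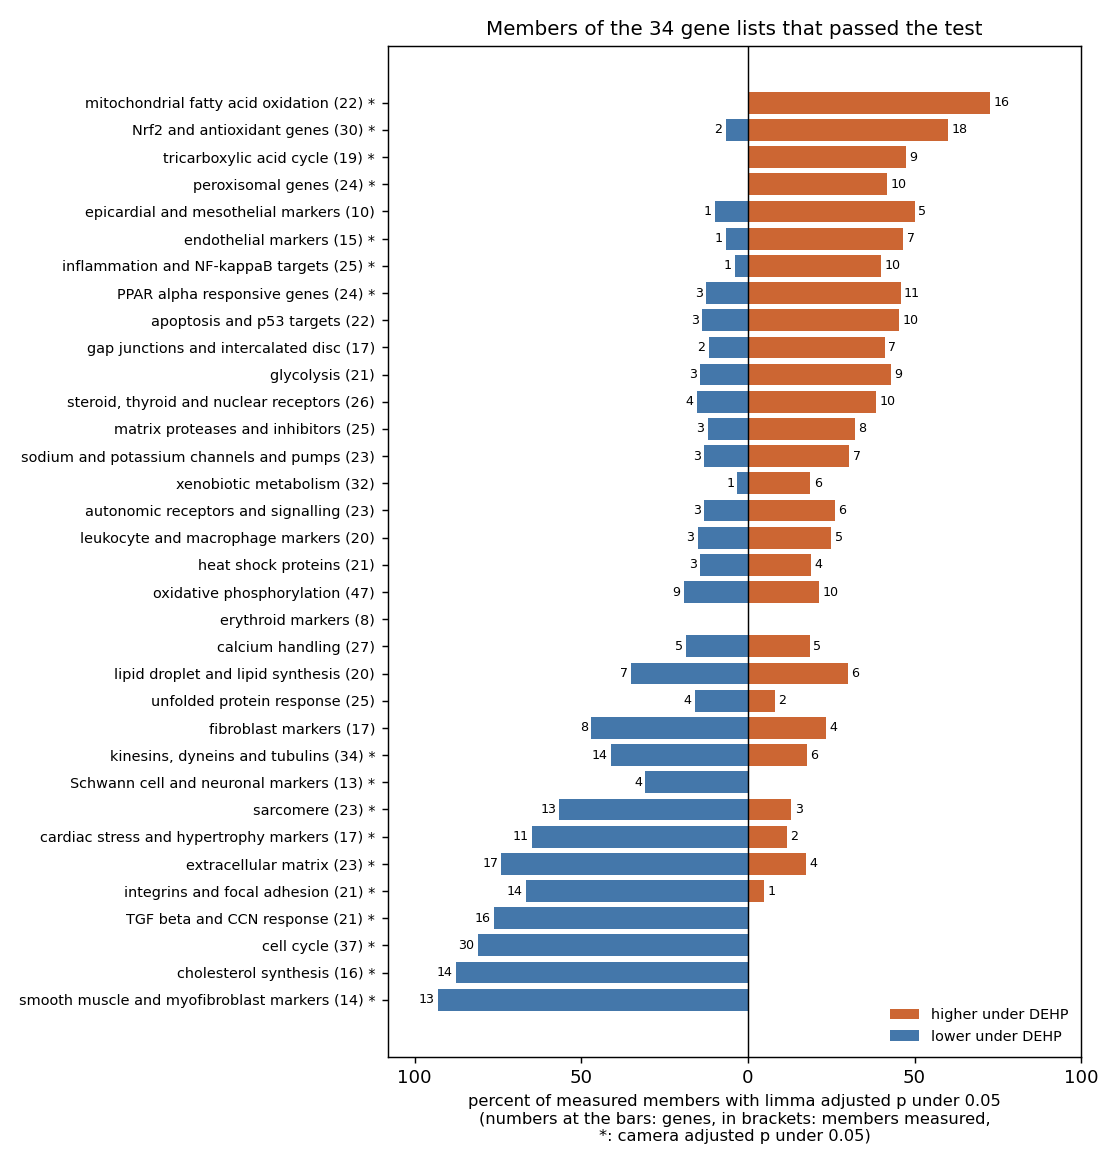
Bars show the percent of the measured members of each of the 34 gene lists that passed the limma test, to the right for genes higher and to the left for genes lower under DEHP, with the number of genes at each bar. Mitochondrial fatty acid oxidation (16 of 22 higher) and smooth muscle markers (13 of 14 lower) mark the ends of the plot.

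Fatty acid oxidation genes were higher under DEHP. Of 22 mitochondrial members, 16 rose, 0 fell and 6 did not pass (16 and 0 adjusted over the list alone), with a median log2 fold of 0.52. The rises included Cpt1b and Cpt1a (1.01 ± 0.08), the muscle and liver forms of the enzyme that commits fatty acids to mitochondrial import, and Ech1 (0.90 ± 0.08). Camera gave this list an adjusted p of 8.34e-11, and adjusted p = 0.20 with an estimated correlation. Its mean was lowest in control replicate 5, at −0.54 against −0.29 to −0.16 in the other controls. Among 24 PPAR alpha responsive genes 11 rose, 3 fell and 10 did not pass (11 and 3 adjusted over the list alone, camera adjusted p = 0.00119, adjusted p = 0.12 with an estimated correlation). Pdk4 and Acot2 rose, and Fads2, a fatty acid desaturase, fell (−1.35 ± 0.07). The list shares 11 of its 28 listed genes with other lists. Ppara itself was 2.42-fold higher (1.27 ± 0.08, adjusted p = 4.41e-07). Pparg (0.02 ± 0.04) and Ppard (0.13 ± 0.08) did not pass, with adjusted p of 0.81 and 0.31, and without DEHP replicate 3 the value of Pparg was −0.01.

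Peroxisomal genes numbered 24 measured members, of which 10 rose, 0 fell and 14 did not pass (11 and 0 adjusted over the list alone). Catalase, Cat, rose (0.82 ± 0.09), as did Hsd17b4 (0.40 ± 0.05) and Phyh (0.86 ± 0.11), enzymes of peroxisomal fatty acid oxidation. The camera adjusted p was 0.000607, and adjusted p = 0.13 with an estimated correlation. In the tricarboxylic acid cycle, 9 of 19 members rose, 0 fell and 10 did not pass (11 and 0 adjusted over the list alone), among them Sdha (0.38 ± 0.06), Ogdh (0.34 ± 0.06) and Pdhx (0.25 ± 0.05). That list had a camera adjusted p of 0.000893, and adjusted p = 0.46 with an estimated correlation. The groups overlapped in its mean, at −0.022 in DEHP replicate 6 and −0.019 in control replicate 3. Control replicate 5 was lowest, at −0.24.

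Cholesterol synthesis genes fell nearly throughout. Of 16 members, 14 fell, 0 rose and 2 did not pass (15 and 0 adjusted over the list alone), with a median log2 fold of −0.67. Cyp51 (−0.99 ± 0.07), Msmo1 (−0.98 ± 0.07) and Dhcr7 (−0.74 ± 0.05), enzymes of the late sterol steps, had the smallest p. The camera adjusted p was 1.71e-13, and adjusted p = 0.067 with an estimated correlation. Lipid droplet and lipid synthesis genes went both ways, with 6 rising, 7 falling and 7 of 20 not passing (7 and 7 adjusted over the list alone, camera adjusted p = 0.99). Acacb, the mitochondrial acetyl-CoA carboxylase, rose (1.42 ± 0.07) while Fads2 fell. The median log2 fold of that list was 0.10 and its mean −0.04.

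Neither glycolysis nor oxidative phosphorylation was called as a list. In glycolysis 9 of 21 members rose, 3 fell and 9 did not pass (9 and 4 adjusted over the list alone). Hk2, a hexokinase, rose by 0.70 ± 0.07 and Ldhb by 0.61 ± 0.06. Its camera adjusted p of 0.058 became 0.020 without DEHP replicate 6, and 0.035, 0.038 and 0.044 without control replicates 1, 2 and 4, and over all arrays the list had adjusted p = 0.46 with an estimated correlation. Of 47 respiratory chain genes, 10 rose, 9 fell and 28 did not pass (11 and 9 adjusted over the list alone, camera adjusted p = 0.62). Ndufs7 of complex I rose (0.47 ± 0.07) and Uqcrq of complex III fell (−0.44 ± 0.06).

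Sarcomere genes fell more often than they rose, with 13 of 23 lower, 3 higher and 7 not passing (16 and 3 adjusted over the list alone). Csrp3, a Z-disc protein, fell by 1.67 ± 0.05 on the log2 scale, and Acta1, skeletal alpha-actin, by 1.25 ± 0.09. Myh6, the fast alpha myosin heavy chain, rose 3.19-fold (1.67 ± 0.12), and cardiac troponin T, Tnnt2, did not pass (−0.05 ± 0.05, adjusted p = 0.54). Camera gave an adjusted p of 1.13e-05, and adjusted p = 0.40 with an estimated correlation. The mean of this list in DEHP replicate 6 was −0.48, below the −0.17 to −0.01 of the other DEHP arrays. Cardiac stress and hypertrophy markers fell in 11 of 17 cases and rose in 2, with 4 not passing (12 and 2 adjusted over the list alone, camera adjusted p = 1.62e-08, adjusted p = 0.018 with an estimated correlation). Besides Edn1 and Xirp2, Hbegf, a growth factor of the EGF family, fell (−1.53 ± 0.05). The atrial natriuretic peptide gene Nppa was 1.74-fold lower (−0.80 ± 0.04, adjusted p = 8.44e-08).

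**Figure D3:**
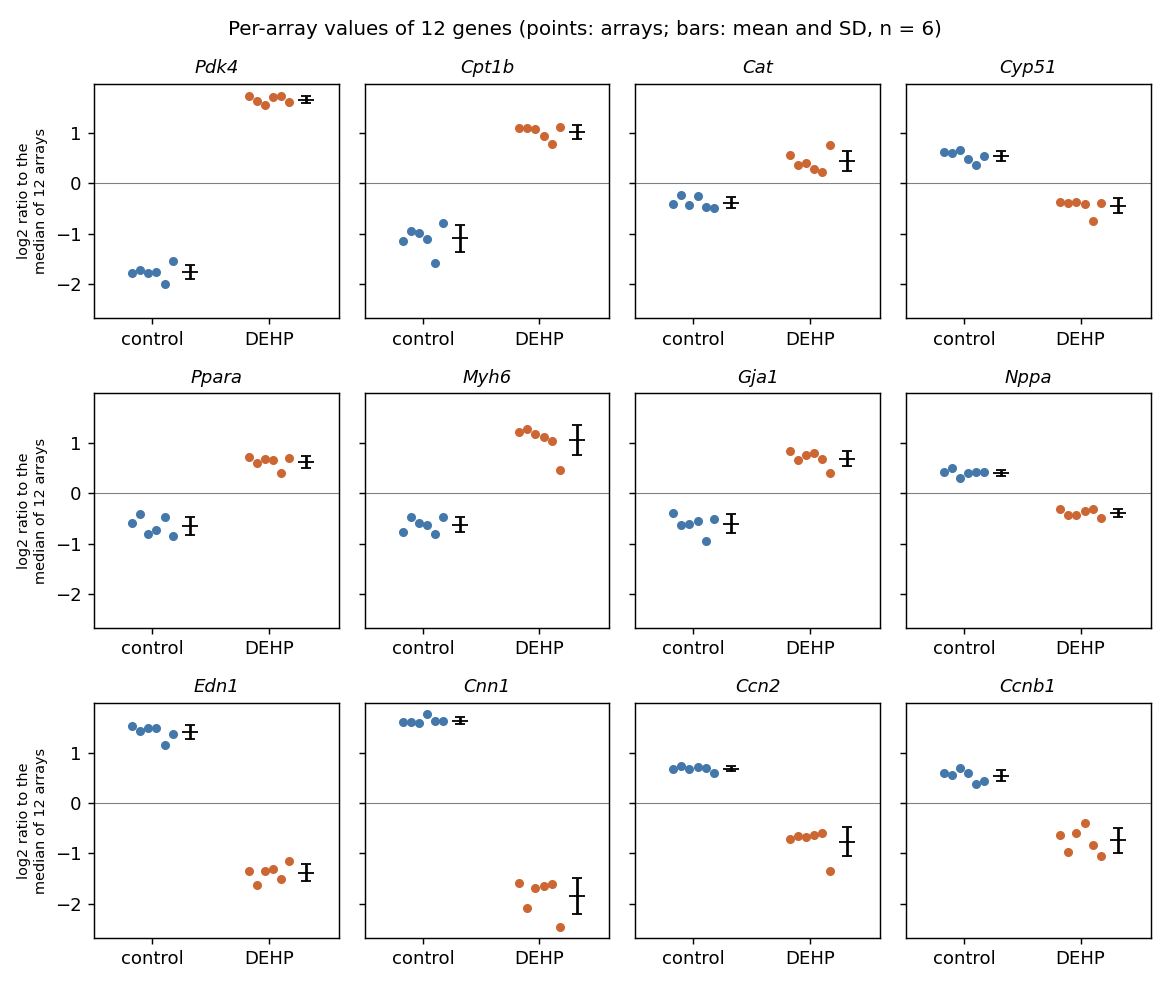
Points show the log2 ratio of 12 genes to their median over the 12 arrays, 1 point per array, with the mean and SD of each group beside them (n = 6). The groups do not overlap in any of these genes, and Pdk4 and Cnn1 show the widest gaps.

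Genes of excitation and conduction moved in both directions. Gja1, which encodes connexin 43, the main ventricular gap junction protein, was 2.46-fold higher (1.30 ± 0.09, adjusted p = 9.54e-07). The desmosomal cadherin Dsc2 also rose (1.28 ± 0.09). Of 17 genes of gap junctions and the intercalated disc, 7 rose, 2 fell and 8 did not pass (8 and 2 adjusted over the list alone), with a camera adjusted p of 0.071 that became 0.043 without control replicate 2, and adjusted p = 0.46 with an estimated correlation over all arrays. In calcium handling 5 of 27 rose, 5 fell and 17 did not pass (7 and 5 adjusted over the list alone, camera adjusted p = 0.39). Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose (1.05 ± 0.07), as did its release channel Ryr2 (1.13 ± 0.10). Sodium and potassium channels and pumps included 7 rises, 3 falls and 13 of 23 not passing (7 and 3 adjusted over the list alone, camera adjusted p = 0.22). Kcnj2, an inward rectifier, rose by 0.87 ± 0.06 and Abcc9, a subunit of ATP-sensitive potassium channels, by 1.57 ± 0.11. Autonomic receptors and signalling genes had 6 rises and 3 falls among 23, with 14 not passing (6 and 3 adjusted over the list alone, camera adjusted p = 0.77). Chrm2, the cardiac muscarinic receptor, rose (1.57 ± 0.09) and Rgs4 fell (−1.31 ± 0.06). The median of that list was −0.01 and its mean 0.03.

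Of 34 kinesins, dyneins and tubulins, 14 fell, 6 rose and 14 did not pass (15 and 7 adjusted over the list alone). When the list was parted after its values were seen, a contrast that was not tested, 10 of the 11 tubulins fell and 1 rose, and 4 of the 23 motors and partners fell and 5 rose. The falls included Tuba1b (−0.95 ± 0.08), Tuba1c (−0.65 ± 0.07) and Tubb4b (−0.64 ± 0.05). Camera gave an adjusted p of 0.022, and adjusted p = 0.46 with an estimated correlation. Integrins and focal adhesion genes fell in 14 of 21 cases and rose in 1, with 6 not passing (15 and 2 adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.037 with an estimated correlation). Itga4 (−1.54 ± 0.13), the actin crosslinker Actn1 (−0.996 ± 0.068) and integrin-linked kinase, Ilk (−0.45 ± 0.04), were among them.

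Matrix genes fell together with TGF beta and CCN genes. Of 23 extracellular matrix genes, 17 fell, 4 rose and 2 did not pass (17 and 5 adjusted over the list alone). Col8a1 (−1.68 ± 0.08) and Fbln2 (−1.48 ± 0.08) fell, and Postn, which encodes periostin, rose (0.47 ± 0.04). The camera adjusted p was 5.8e-06, and adjusted p = 0.30 with an estimated correlation. Smooth muscle markers fell in the same arrays, and the matrix mean in DEHP replicate 6 was −0.42 against −0.19 to −0.13 in the other DEHP arrays. In the TGF beta and CCN list 16 of 21 members fell, 0 rose and 5 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 9.03e-12, adjusted p = 0.033 with an estimated correlation). Ccn3 (−1.69 ± 0.06), Ccn2, the connective tissue growth factor (−1.45 ± 0.11), and Ltbp2, a microfibril protein of the matrix (−1.15 ± 0.08), had the smallest p. Matrix proteases and inhibitors had 8 rises and 3 falls among 25, with 14 not passing (9 and 3 adjusted over the list alone). Mmp2 rose (0.70 ± 0.05) and the inhibitor gene Timp3 fell (−1.42 ± 0.11). Their camera adjusted p of 0.094 became 0.014 without DEHP replicate 6, and over all arrays they had adjusted p = 0.46 with an estimated correlation.

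Markers of other cell types did not move as one. Smooth muscle and myofibroblast markers fell in 13 of 14 cases, with 0 rises and 1 not passing (13 and 0 adjusted over the list alone, camera adjusted p = 2.05e-12, adjusted p = 0.12 with an estimated correlation). Beside Cnn1, smooth muscle myosin, Myh11 (−1.68 ± 0.10), and the potassium channel subunit Kcnmb1 (−1.59 ± 0.08) fell. The list mean was lowest in DEHP replicate 6, at −0.99 against −0.60 to −0.41. Of 17 fibroblast markers 8 fell, 4 rose and 5 did not pass (8 and 4 adjusted over the list alone, camera adjusted p = 0.12). Mfap5 fell (−1.83 ± 0.09) and the receptor gene Pdgfra rose (0.90 ± 0.07). Endothelial markers rose in 7 of 15 cases and fell in 1, with 7 not passing (10 and 1 adjusted over the list alone, camera adjusted p = 0.0051, adjusted p = 0.48 with an estimated correlation). Their mean was −0.26 in DEHP replicate 6 against 0.12 to 0.35 in the other DEHP arrays, and without that array the camera adjusted p was 0.000128. Tie1 (0.58 ± 0.11) and Fabp4 (0.89 ± 0.17) rose and Flt1, a VEGF receptor, fell (−0.74 ± 0.10). Fabp4, a fatty acid carrier that fat cells also make, had an adjusted p of 0.057 after cyclic loess.

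Leukocyte and macrophage markers had 5 rises and 3 falls among 20, with 12 not passing (5 and 3 adjusted over the list alone, camera adjusted p = 0.66). Itgam rose (0.53 ± 0.09) and Csf1r fell (−0.41 ± 0.06). Of 10 epicardial and mesothelial markers 5 rose, 1 fell and 4 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.43), with Wt1 at 0.29 ± 0.05 and Gpm6a at 0.48 ± 0.10. Schwann cell and neuronal markers fell in 4 of 13 cases, with 0 rises and 9 not passing (4 and 0 adjusted over the list alone, camera adjusted p = 0.0051, adjusted p = 0.28 with an estimated correlation). These were led by Uchl1 (−1.13 ± 0.06), a ubiquitin hydrolase, the tubulin Tubb3 (−0.99 ± 0.11) and the myelin protein gene Pmp22 (−0.30 ± 0.06). Tubb3 is also in the tubulin list. Members that did not pass, chosen after their values were seen, included Sox10 (−0.18 ± 0.10), Mbp (−0.02 ± 0.07) and Cdh19 (−0.004 ± 0.03). None of 8 erythroid markers passed limma, so 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.45). The smallest unadjusted p there were 0.039 for Hbb (−0.25 ± 0.11) and 0.048 for Slc25a37 (0.43 ± 0.20, and 0.22 without DEHP replicate 6). Hbb had an adjusted limma p of 0.026 with the replicate block, 0.013 with array weights and 0.032 without DEHP replicate 5.

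Cell cycle genes fell in 30 of 37 cases, with 0 rises and 7 not passing (34 and 0 adjusted over the list alone) and a median log2 fold of −0.59. Ccnb1 (−1.29 ± 0.10) and Ccnb2 (−1.11 ± 0.08), the B-type cyclins of mitosis, and Cdc20 (−0.85 ± 0.07), an activator of the anaphase-promoting complex, had the smallest p. Camera gave an adjusted p of 3.23e-18, and adjusted p = 0.19 with an estimated correlation. Of 22 apoptosis genes and p53 targets, 10 rose, 3 fell and 9 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.10). Bcl2l11, which encodes the proapoptotic protein BIM, rose (0.77 ± 0.08), as did Gadd45a (0.49 ± 0.05).

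Antioxidant genes rose. Of 30 Nrf2 and antioxidant genes, 18 rose, 2 fell and 10 did not pass (19 and 2 adjusted over the list alone, camera adjusted p = 7.46e-07, adjusted p = 0.20 with an estimated correlation). The metallothionein genes Mt1 (1.15 ± 0.08) and Mt2A (0.74 ± 0.07), which respond to metals and glucocorticoids too, and ferritin heavy chain, Fth1 (0.52 ± 0.04), had the smallest p. The mean of this list was highest in DEHP replicate 6, at 0.39 against 0.05 to 0.17. In the unfolded protein response 2 of 25 genes rose, 4 fell and 19 did not pass (2 and 5 adjusted over the list alone, camera adjusted p = 0.89), and the rises were those of Ddit3 (0.77 ± 0.08) and Trib3 (0.83 ± 0.11). Its median log2 fold was −0.0017 and its mean 0.03. Heat shock proteins included 4 rises and 3 falls among 21, with 14 not passing (4 and 3 adjusted over the list alone, camera adjusted p = 0.99). Hspb3 and Cryab, alpha-B crystallin (−0.63 ± 0.06), fell, and the list had a median of 0.03 and a mean of −0.09.

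Xenobiotic metabolism had 6 rises and 1 fall among 32 genes, with 25 not passing (6 and 1 adjusted over the list alone, camera adjusted p = 0.36). The drug exporters Abcb1b (1.18 ± 0.15) and Abcc4 (0.80 ± 0.11) rose, and the list had a median of −0.0081 and a mean of 0.10. Of 26 steroid, thyroid and other nuclear receptors and coactivators, 10 rose, 4 fell and 12 did not pass (10 and 4 adjusted over the list alone, camera adjusted p = 0.17). Ppara rose and Nr4a3, an orphan receptor of the immediate-early response, fell (−1.26 ± 0.07).

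Inflammation and NF-kappaB targets rose in 10 of 25 cases and fell in 1, with 14 not passing (13 and 1 adjusted over the list alone). The chemokine genes Cxcl11 and Cxcl10 (1.16 ± 0.19) and the adhesion molecule Vcam1 (1.19 ± 0.17) had the smallest p. Camera gave an adjusted p of 0.00153, and adjusted p = 0.53 with an estimated correlation. The list mean was 1.37 in DEHP replicate 6 against 0.04 to 0.13 in the other DEHP arrays and −0.26 to −0.08 in controls. Without that array 12 members rose, 5 fell and camera gave an adjusted p of 0.023.

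**Figure D4:**
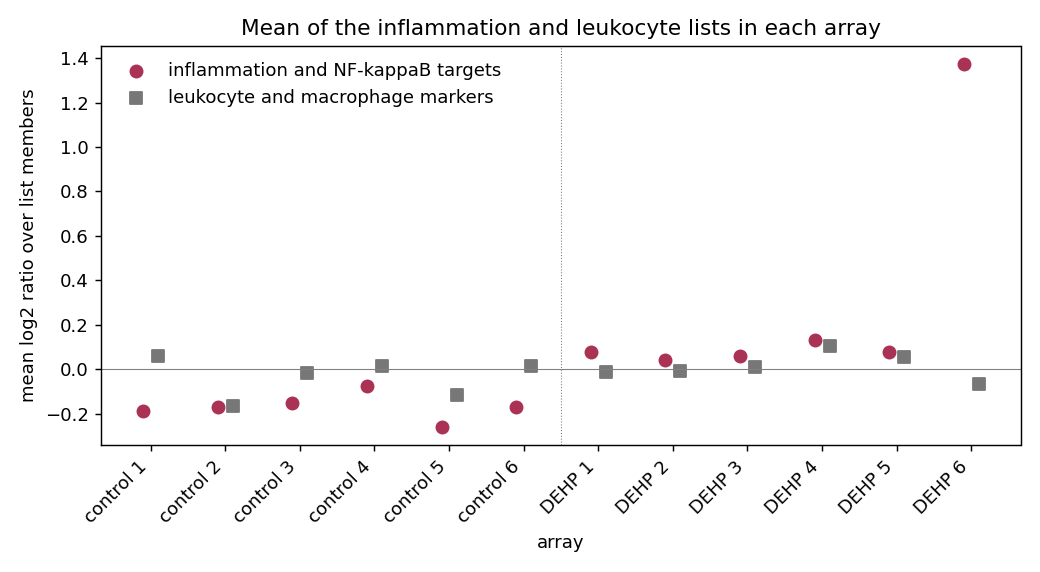
The vertical axis gives the mean log2 ratio over the measured members of the inflammation list (circles, 25 genes) and of the leukocyte list (squares, 20 genes), with the 12 arrays along the horizontal axis. DEHP replicate 6 has an inflammation mean of 1.37 and a leukocyte mean of −0.07, and no other array has an inflammation mean above 0.133.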

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

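For each group of 6 arrays, the distance of the highest or lowest array from its nearest neighbour was divided by the range of the group, and values above the 95% critical value of Dixon's test are given here as gap ratios. This was done for the mean of each list, for each gene named by the rule and for the SD of log2 ratios, 278 groups in all. The ratio was exceeded in 57, where chance gives about 13.9, since about 1 in 20 groups passes by chance. DEHP replicate 6 accounted for 33, control replicate 5 for 17 and other arrays for 7. Of the tests below, those of noise, leukocytes, shared array or RNA quality, and cell shares were chosen after the values they rest on were seen.

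The mean of the inflammation list was far higher in DEHP replicate 6 than in the other DEHP arrays (gap ratio 0.933). Without that array 12 members still rose and 5 fell under DEHP. Chosen after their values were seen, Serpinb2 was 21.3-fold, Ccl20 14.4-fold, Csf3 13.5-fold and Il1b 12.8-fold above the mean of the other 5 DEHP arrays, while Il1b was lower than in controls without that array (log2 fold −0.79, adjusted p = 1.16e-05). The tables argue against an untreated culture with a wrong label, since 99% of 200 genes differed from control in the DEHP direction. More leukocytes were not seen in their markers, whose mean was −0.096 relative to the other 5 DEHP arrays. Lyz2 lay at −0.42 and Ptprc at −0.02 from their mean, although Cd14 was higher by 0.96. Of these 20 markers, 3 lay above and 11 below all other DEHP arrays. A change of state could shift such markers too, so they do not settle the number of leukocytes. Noise of 1 array, independent between genes, is argued against as well, since 23 of the 25 members lay above all other DEHP arrays (at most 15 in 10000 random lists of that size) and the mean deviation of 1.29 exceeded 100% of those random lists (at most 0.33) and the 33 other fixed lists (at most 0.51 in either direction). None of these 20 markers is in another list, no sort of the cells is named, marker levels are not held in the ratios, and an activated state of that culture, such as contact with a microbial product, stays open and was not tested.

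Control replicate 5 had the widest spread of log2 ratios (SD 0.37, gap ratio 0.849). A swap with a DEHP culture is argued against, since 2% of 200 genes lay nearer to the DEHP mean in that array. Array or RNA quality shared with other arrays cannot be told apart. Probe sets without a gene name spread 98.96% as much as named ones there, against 69.5% to 92.0% in the other arrays. The deviation of control replicate 5 from the other controls correlated across probe sets with those of DEHP replicates 1 to 6 by −0.40, 0.55, −0.43, −0.51, 0.77 and −0.31, but deviations within a group sum to 0, so both signs arise, and the highest such value of the other controls, with control replicate 5 left out, was 0.21 to 0.45 and over 0.3 in 3 of 5. The 0.77 was with DEHP replicate 5, the array of the same number, and lay above the 0.21 to 0.45 of the other controls. No batch is given in the labels, and no biological explanation was tested.

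Smooth muscle markers fell while fibroblast and sarcomere genes moved both ways under DEHP. Fewer fibroblasts and other non-myocytes alone do not account for the 4 fibroblast markers that rose, Pdgfra, Dcn, Fmod and Lum, or the endothelial rises. But 8 fibroblast markers fell, and 2067 of all 14324 genes rose, so a few rises in a list of 17 decide little. Fewer of these cells thus stays open as a part of the change. A larger share of cardiomyocytes as the whole cause is argued against by the 13 sarcomere genes that fell. It also stays open as a part of the change. The 3 of 23 sarcomere genes that rose, among them Myh6, are no evidence for it at that overall share of rises. Ryr2 and Atp2a2 rose too, but calcium handling had 5 rises and 5 falls, the falls including Casq2, Sln and Jph2. A change of state within smooth muscle cells or myofibroblasts, or fewer of these cells alone, stays open, and DEHP itself is the biological difference in the design.

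In DEHP replicate 6 the means of several other lists lay lowest among DEHP arrays. The gap ratio was 0.654 for sarcomere, 0.633 for sodium and potassium channels, 0.724 for autonomic receptors, 0.794 for extracellular matrix, 0.751 for fibroblast markers and 0.675 for smooth muscle markers, and 0.635 for Nrf2 and antioxidant genes, which lay highest. The SD of its log2 ratios was 0.27 (gap ratio 0.699). Genes lowest there were Penk (0.789), Tgfb3 (0.661), Arsi (0.731), Myh6 (0.704), Tnnt2 (0.674), Ech1 (0.698), Acta1 (0.718), Atp2a2 (0.680), Rgs4 (0.631), Chrm2 (0.661), Fbln2 (0.780), Timp3 (0.708), Gpm6a (0.719), Tubb3 (0.719), Pmp22 (0.794) and Ccn2 (0.835). Highest there were Hp (0.879), Ampd3 (0.745), Pdgfra (0.795), Slc25a37 (0.825), Abcb1b (0.715), Abcc4 (0.684), Vcam1 (0.901) and Cxcl10 (0.718). The log2 ratio of Hp was 2.52 in that array and 0.57 to 0.81 in the other DEHP arrays, and that of Penk was 0.73 against 2.29 to 2.71.

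Control replicate 5 held the lowest mean among controls for fatty acid oxidation (gap ratio 0.656), peroxisomal genes (0.756), lipid droplets and lipid synthesis (0.876), gap junctions (0.631), kinesins, dyneins and tubulins (0.663), apoptosis (0.662), Nrf2 and antioxidant genes (0.744) and heat shock proteins (0.809). Its genes lowest among controls were Acsl1 (0.843), Hspb3 (0.766), Cpt1a (0.756), Phyh (0.71), Uqcrq (0.647), Timp3 (0.711), Cdc20 (0.698) and Ddit3 (0.850). In other arrays, Pla2g7 (0.731) and Cyp51 (0.892) were lowest in DEHP replicate 5, Mmp2 (0.632) was lowest in DEHP replicate 3, Ryr2 (0.686) was highest in DEHP replicate 2 and Col8a1 (0.803) in DEHP replicate 4. Cnn1 (0.802) was highest in control replicate 4 and Kcnmb1 (0.656) in control replicate 6.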

How the results depend on the processing

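All 3 counts (probe sets, genes and lists) stayed within 1.5 times their value under quantile normalization, the replicate block, each array left out in turn and, chosen after seeing the data, both arrays that stand apart left out. Leaving out each array in turn gave 4211 to 5556 probe sets, 2997 to 3888 genes and 17 to 19 lists, and all 17 lists were called each time. Median centring, cyclic loess and robust eBayes (the last chosen after seeing the data) also kept the counts of probe sets and genes within that range. Array weights called 7614 probe sets and the cause was not tested, though control replicate 5 had the lowest weight (0.14). Stricter tests called fewer by construction, with 1182 probe sets and 870 genes against a minimum fold of 1.2, and 3238 and 2339 at an adjusted p under 0.01. Camera with an estimated correlation called 3 lists, or 5 with both arrays that stand apart left out, when PPAR alpha and smooth muscle lists passed too, since correlated members widen its null. Fry, which compares a list with no other genes, called 25 lists, 16 of them among the 17. Of 104 named genes 100 kept their direction and side of the threshold under the replicate block, the 3 normalizations, robust eBayes, array weights, the mean of all probe sets of a gene, each array left out in turn and both arrays left out. Of the 99 that passed, 87 passed against a minimum fold of 1.2, where Hsd17b4, Sdha, Ogdh, Pdhx, Uqcrq, Ndufs7, Tie1, Csf1r, Itgam, Wt1, Gpm6a and Pmp22 did not, and 99 passed at an adjusted p under 0.01. The log2 fold of Penk was −0.010 after cyclic loess, for which the cause was not tested, and Fabp4 lost its call there. Since the ratios hold no level, cyclic loess ran along mean log2 ratios and not along intensity, which limits what it says of both genes. Hbb gained a call with the replicate block, with array weights and without DEHP replicate 5. Pparg, which did not pass, ranged from −0.0053 to 0.041 with 1 array left out. Among lists that were not called, the direction given by the test, which rests on t statistics, went from up to down for the unfolded protein response and heat shock proteins under quantile normalization and with both arrays left out, and for lipid droplets and heat shock proteins with fry. The mean log2 fold of a list minus that of all genes turned in 1 of these cases, the unfolded protein response with both arrays left out (0.026 to −0.0082), while it was 0.0069 for that list under quantile normalization, below 0 throughout for heat shock proteins (−0.10 as deposited and with fry, −0.11 and −0.12 otherwise) and −0.043 for lipid droplets with camera and fry alike. With 1 array left out the direction given by camera also went from up to down, at an adjusted p of 0.598 or more, for oxidative phosphorylation without control replicate 5 or DEHP replicate 3 (0.0015 and 0.0081, from 0.031 over all arrays), the unfolded protein response without control replicate 5 or DEHP replicate 6 (0.0012 and 0.016), lipid droplets without control replicate 5 or 6 or DEHP replicate 1, 3 or 4 (−0.074 to −0.039) and heat shock proteins without control replicate 5 or DEHP replicate 1, 3, 4 or 6 (−0.13 to −0.093), and in none of these did the mean turn. With the replicate block 6541 probe sets, 4352 genes and 17 lists passed. The labels tie nothing to these numbers, and deviations of same-numbered arrays correlated by 0.34, 0.13, 0.35, 0.25, 0.77 and 0.07, with 5 of the 12 arrays correlating best with their own number. Of the 6 pairs 5 lay above 0.1 and 1 did not, a hint from the data and not the design, so the numbers were not taken as pairs. The filter on dim probe sets and eBayes with an intensity trend were not run, since the ratios hold no level, and signal over background limits what can be said of weakly expressed genes.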

Other observations

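Further members of the fixed lists, chosen after their values were seen, filled out the account. The orphan receptor genes Nr4a1 (log2 fold −0.90 ± 0.08) and Nr4a2 (−1.46 ± 0.14) fell along with Nr4a3. The coactivator genes Ppargc1a (0.85 ± 0.11) and Ppargc1b (0.66 ± 0.08) and the receptor gene Esrrg (0.64 ± 0.08), known regulators of mitochondrial metabolism, rose. Cd36, which encodes a fatty acid transporter, rose (1.199 ± 0.156), as did Angptl4 (1.62 ± 0.30), an inhibitor of lipoprotein lipase, while the desaturase gene Scd fell (−1.35 ± 0.08). Tgfb2 (−1.40 ± 0.14), Inhba (−1.33 ± 0.12) and Bmp4 (−1.25 ± 0.11) fell, while Tgfb1 (−0.10 ± 0.08) and Bmp2 (0.33 ± 0.36, and −0.05 without DEHP replicate 6) did not pass. The detoxifying enzymes Gstp1 (1.05 ± 0.12) and Nqo1 (1.02 ± 0.25) and the stress cytokine Gdf15 (1.04 ± 0.22) rose.

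To follow these patterns, 4 further lists were written after the report's results, but before their own values were seen. Interferon-stimulated genes rose in 14 of 23 cases and fell in 2, with Mx2 (1.42 ± 0.16), Rsad2 (1.43 ± 0.20) and Isg15 (0.85 ± 0.11) among the rises and Ifit2 (−0.38 ± 0.08) and Ifit1 (−0.27 ± 0.07) lower. Actin cytoskeleton targets of serum response factor fell in 16 of 18 cases with 0 rises, led by Flna (−0.94 ± 0.05), Tpm2 (−1.04 ± 0.08) and Myl9 (−1.32 ± 0.13). Of YAP and TEAD targets 8 of 16 were measured, and 7 fell with 0 rises, among them Lats2 (−0.75 ± 0.04), F3 (−0.81 ± 0.07) and Amotl2 (−0.72 ± 0.07). Targets of the sterol-sensing receptor LXR had 1 rise and 3 falls among 9. Apoe rose (1.205 ± 0.089) and Abcg1 fell (−0.70 ± 0.07).

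Lower serum response factor activity may accompany the fall of smooth muscle and stress genes. The list of its further targets fell with a camera p of 5.35e-15 (adjusted p = 2.14e-14 over the 4 lists, p = 0.024 with an estimated correlation), and Srf itself fell (−0.36 ± 0.07). Fewer smooth muscle cells or myofibroblasts, which stays open, would lower contractile genes of this list such as Myl9 and Tpm2 too, so the test does not tell this from lower activity. Lower YAP and TEAD activity is a second hypothesis, for the fall of CCN genes and Edn1, with a camera p of 6.16e-07 (adjusted p = 8.21e-07, p = 0.0018 with an estimated correlation). Fewer smooth muscle cells or myofibroblasts could lower this list as well, and the test does not tell that from lower activity. Targets of both regulators overlap in biology, so these results do not tell one from the other, and neither protein was measured.

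An interferon response is a hypothesis for the rise of Cxcl10 and Cxcl11. Without DEHP replicate 6 the interferon list rose with a camera p of 2.98e-08. Over all arrays camera gave p = 3.86e-07, and p = 0.14 with an estimated correlation. On that last measure the hypothesis is weaker than those of serum response factor and YAP, but no such estimate was made without DEHP replicate 6. Sterol excess in the cells was a hypothesis for the fall of cholesterol synthesis genes. Its prediction, a rise of LXR targets, was not met (camera adjusted p = 0.40 over the 4 lists, direction down). With 9 targets measured, 1 higher and 3 lower, that list does not exclude sterol excess. What else could lower these genes was not tested.

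Other splits of the 12 arrays into 6 and 6 were used to ask whether chance could give as many calls. In 100 splits, the real one included, 1 gave 5016 probe sets or more and 1 gave 3527 genes or more, which was the real split in both cases, and the highest of the others gave 0 of either. The other splits put arrays of both groups on each side, so the difference between the groups widens their spread and lowers their calls. They are not a clean measure of chance, and for both counts show only that the real split stood alone. For the 17 lists 5 of 100 splits called as many and the highest of the others called 18, so this count does not exclude chance. The other 4 of these splits kept 4 or 5 of the 6 controls together and so held part of the difference between the groups. The 44 splits that kept 3 together called at most 11, so the count does not show that chance gives as many lists either. Yet those splits held no net difference between the groups, and nearly all of them called lists. Camera at the preset correlation thus calls lists here without such a difference, so its p alone overstates the evidence for a list.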
